A study of Mus musculus with 2 samples.

How the data were processed

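H3K36me3 ChIP-seq peak lists from limbs of mouse embryos at embryonic day 10.5 were analysed, in 1 group of 2 biological replicates made from pools of 69 and 51 embryos of both sexes, per the labels. Per the labels, replicate 1 joined technical replicates 1 and 2, replicate 2 had 1 technical replicate, and fragments of 300 to 500 bp were sequenced. The authors deposited 4 peak lists on mm10, one for each replicate, one called on both replicates together and a replicated list, all of whose 189804 peaks were in the pooled list with the same coordinates. How a pooled peak qualified as replicated, the aligner, the peak caller, its control and its settings are not given in the sources used here. No peak had a −log10 p under 2.00.

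Each deposited peak carries a signal, the authors' enrichment value for that peak, whose scale is not given in the sources used here, so it was used to describe and rank peaks within a list and, between the replicate lists, only for a correlation at overlapping peaks. Each deposited peak also carries a −log10 p and a −log10 q, by column order, and these were used only to filter peaks. The plan, written before the data were examined, called the signal a fold enrichment. Depth is unknown for both replicates, because the peak lists give no read counts. No interval or detection floor was therefore computed, and a gene with no peak had no peak called, which does not show that the mark was absent. A peak covers a place whether the mark lay there in most cells or in some, so percent cover is neither an amount of the mark nor of RNA. The caller split the mark into pieces differently in the replicates (median widths of 158 bp and 348 bp), which affects peak numbers more than covered bases.

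The groups of samples, the tests, 33 gene lists, the settings and their alternatives, and the rule for named genes were fixed before the data were examined. Genes came from GENCODE M21 on the same build. Protein-coding genes with a symbol on chromosomes 1 to 19, X and Y and a span of at least 1 kb were tested, 21196 in all, using the longest span of each symbol. Of 2346 list members 2339 matched such a gene. The percent of each span covered by peaks was computed for each list. A gene was called marked at 10% or more cover by the replicated peaks, and alternatives used 5% and 20%. Values with a mean ± SD are over the 2 replicate lists, and values without one come from the replicated list unless a replicate is named.

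Peaks of the replicates were shared when they overlapped by at least 1 bp, and chance overlap came from 100 circular rotations within chromosomes (one-sided permutation, smallest p 0.0099). The same rotations served the location of peaks, with promoters taken as 1 kb on either side of a gene start. The profile along genes used 10 equal parts and flanks of 10 kb in marked genes of at least 10 kb. Each list median was compared with 10000 random lists from the other genes, matched in 20 bins of gene length (two-sided permutation, smallest p 0.0002), with Benjamini-Hochberg adjustment over 33 lists. Random lists take genes as exchangeable, while neighbouring and overlapping genes share peaks, so the p-values describe the genes of these 2 pools and not a spread between animals. A test of the number of marked members was added after the data were seen.

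Alternatives were the peaks of either replicate alone, peaks with a −log10 q of at least 2, the pooled list, peaks under 1 kb apart merged, an overlap of at least 50% of the peak, equal numbers of peaks in both replicates, no matching on length, genes of at least 5 kb, and spans without their first 1 kb. Added after the data were seen were the count of marked members, marked calls in both replicates alone, exons against introns within 10 equal parts of the gene, places by peak midpoint, and replicated peaks that overlapped a peak of each replicate list.

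The rule for named genes was as follows. Always named were Tbx5, Tbx4, Pitx1, Prrx1, Hand2, Shh, Fgf8, Gli3, Grem1, Lmx1b, Meis1, Hoxa13, Hoxd13, Sox9, Pax3 and Setd2. Also named were up to 2 members of each list with the highest and up to 2 with the lowest cover, the 10 genes of at least 10 kb with the highest cover and the 5 peaks with the highest signal. Members named because 5 or fewer of a list were marked (Hoxa11, Hoxd10, Col9a1, Cx3cr1), the genes Epor, Kdm5d, Ddx3y and Eif4a1, and all further genes of the closing part were chosen after their values were seen, unless they belong to a list said there to be written first.

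The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Interval cover was checked on simulated intervals (0 of 5000 queries wrong), and the numbers of shared peaks were identical with bedtools 2.31.1. The list test was tested on simulated data made by shuffling the cover of 21196 genes within length bins, with 100 lists of 20 genes at each size of shift and 1000 random lists. With no shift 2 lists had a p under 0.05 and 0 after adjustment. With cover raised by 30 percentage points 62 had a p under 0.05 but only 12 after adjustment, and with 60 points all 100 passed both. The size of 60 points was put in after recovery at 30 points had fallen short of the 80% that the check asked for. The list test therefore detects large upward shifts and misses many upward shifts of moderate size. No downward shift was simulated. With the replicated peaks the lower bound of the random lists was 0 for every list, so the test could not call a list low. Of genes with less than 5% cover raised by 20 percentage points 100 of 100 were called marked, and of genes raised by 2 points 0 of 100. Both counts follow from the threshold for a marked gene by arithmetic. They check only that the threshold was applied, and not how well marked genes are recognised.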

Results

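The data recorded where histone H3 trimethylated at lysine 36 (H3K36me3), a histone mark deposited across the bodies of transcribed genes, lay in the genome of the mouse limb at embryonic day 10.5. At this age the limb is a bud of proliferating mesenchyme under a thin ectoderm. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on limb tissue of B6NCrl embryos of both sexes, in 1 group of 2 biological replicates. Replicate 1 was a pool of 69 embryos and replicate 2 a pool of 51 embryos. There was no second tissue, age or genotype, so the comparisons are between the replicates, between parts of the genome and between groups of genes. Peaks called on each replicate alone, peaks called on both together, and the subset of the latter listed as replicated were used. Read depth is unknown, because the peak lists carry no read counts. Each peak's signal is the authors' own value and was used within a list and, between the replicates, for a correlation. All coordinates are on mm10.

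The same genes carried the mark in both replicates. The percent of the gene span covered by peaks had a Pearson correlation of 0.988 and a Spearman correlation of 0.965 across 21196 protein-coding genes, which are not independent replicates. With a gene called marked when at least 10% of its span was covered, 8418 genes were marked in both replicates, 57 in replicate 1 alone and 583 in replicate 2 alone, so that 97.0% of genes had the same call. Cover was higher in replicate 2 at 7953 of the 8676 genes marked by the replicated peaks, with a median difference of 5.81 percentage points. The hindlimb regulators Tbx4 and Pitx1 stood far from that median, at 40.5% in replicate 1 against 73.7% in replicate 2 and at 1.98% against 30.4%. Pitx1, at 6.14% by the replicated peaks, was not itself among those marked genes. The forelimb regulator Tbx5 had 83.5% and 82.5%. These genes lay at chromosome 11, 85886422 to 85916097 (Tbx4), chromosome 13, 55825051 to 55836192 (Pitx1), and chromosome 5, 119832668 to 119885219 (Tbx5).

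**Figure D1:**
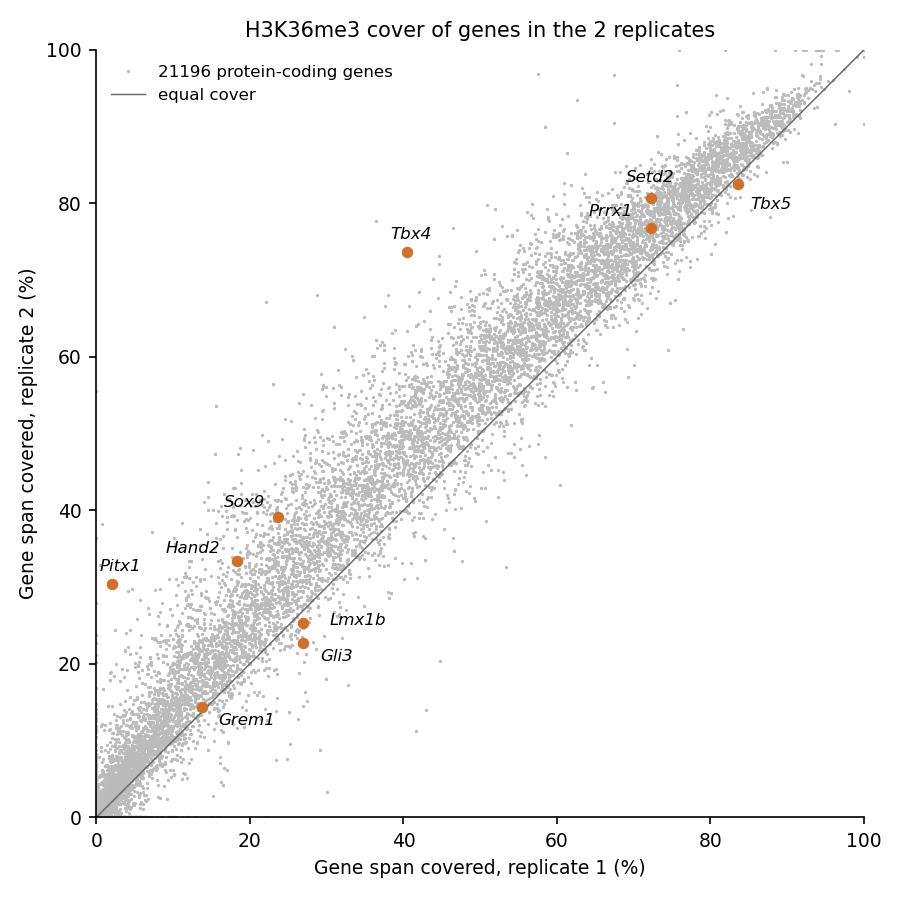
Percent of the gene span covered by H3K36me3 peaks in replicate 1 (x axis) and replicate 2 (y axis), with 1 grey point for each of 21196 protein-coding genes, genes fixed in advance in orange and a line of equal cover. Of the points 10216 lie above the line, 2528 below it and 8452 on it; Tbx5 lies near it at 83.5% and 82.5%, and Tbx4 lies far above it at 40.5% and 73.7%.

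**Figure D2:**
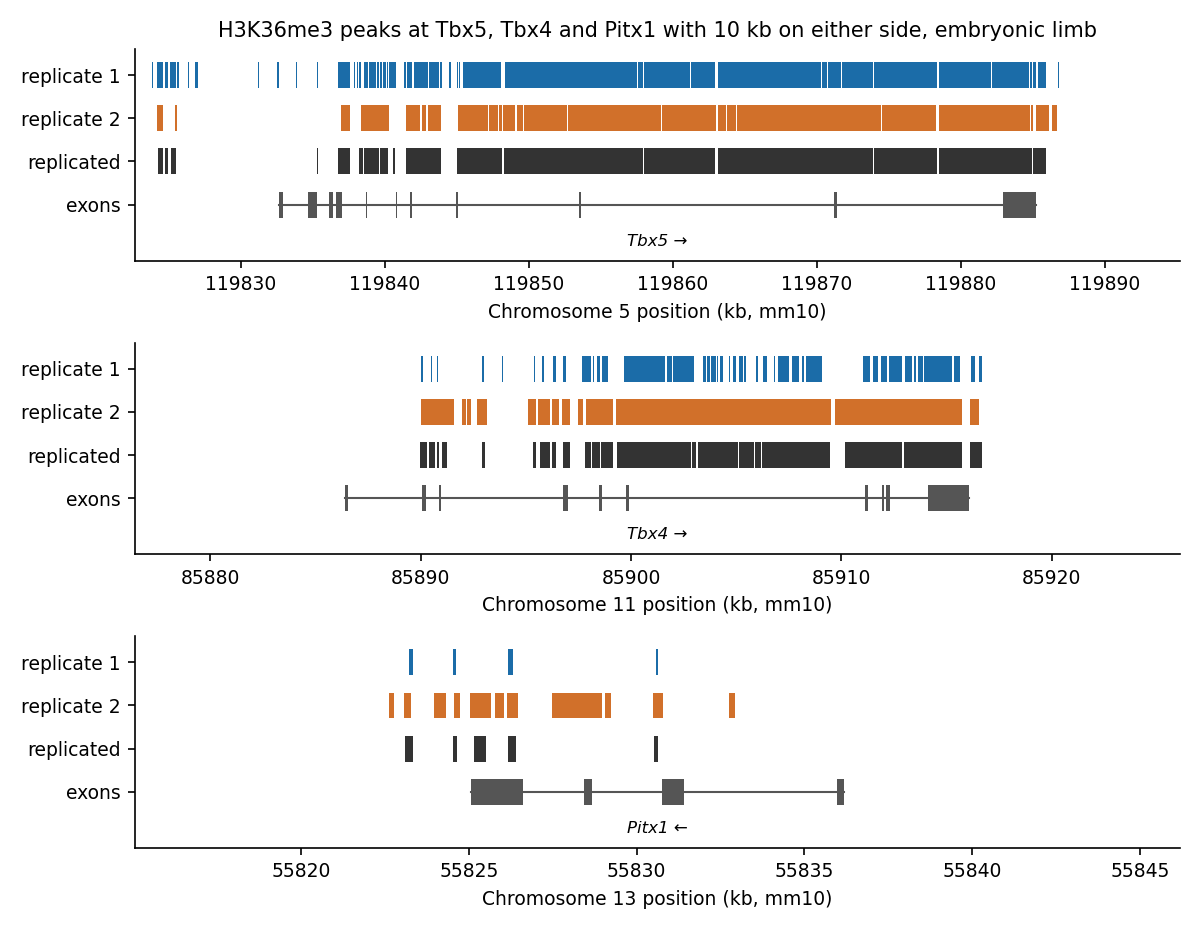
Peaks of replicate 1, peaks of replicate 2, replicated peaks and annotated exons at Tbx5, Tbx4 and Pitx1, with 10 kb on either side and mm10 positions in kb on the x axis; arrows give the direction of transcription. Peaks cover 83.5% and 82.5% of Tbx5 in the replicates, while cover is higher in replicate 2 at Tbx4 (40.5% and 73.7%) and Pitx1 (1.98% and 30.4%).

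The replicate lists differed in form more than in place. Replicate 1 gave 352134 peaks with a median width of 158 bp and replicate 2 gave 195547 peaks with a median width of 348 bp. They covered 132.3 Mb and 157.0 Mb, with a mean of 145 ± 17.5 Mb (SD, n = 2). Of the peaks of replicate 1, 74.2% overlapped a peak of replicate 2 by at least 1 bp, and 77.1% of the peaks of replicate 2 overlapped a peak of replicate 1. After circular rotation of one list within each chromosome the highest shares of 100 rotations were 9.28% and 10.2% (one-sided permutation p = 0.0099 for each direction, the smallest that 100 rotations can give). Rotation does not keep peaks in genes, so it cannot tell agreement of the replicates from a preference for genes in both lists. The shared peaks held 92.5% and 93.5% of the peak bases, and the peaks without a partner were narrow, with median widths of 95 bp and 196 bp. Bases covered in both replicates made up 65.7% of the bases covered in either. Peak signal at 150755 overlapping pairs had a Spearman correlation of 0.610 and a Pearson correlation of 0.753 across peaks.

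The replicated list held 189804 of the 275399 pooled peaks and 93.2% of their bases, and covered 148.1 Mb or 5.59% of the sequenced genome. Its median signal was 3.72 against 2.60 for the 85595 other pooled peaks, and its median width was 358 bp against 113 bp. A peak of replicate 1 overlapped 94.0% of the replicated peaks and a peak of replicate 2 overlapped 92.3%, while 87.1% overlapped a peak of each. Membership in this list therefore did not require a peak in each replicate list.

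The peaks lay inside genes. Protein-coding gene spans held 94.4% of the replicated peak bases against 39.2% of the genome, a ratio of 2.41. Exons were the most enriched part at 5.81 times their share of the genome, and introns followed at 2.06 times. The kilobase on either side of gene starts was depleted to 0.304 times its share, other annotated genes to 0.149 times, and sequence between annotated genes to 0.0844 times. Each of these 6 ratios lay outside 100 circular rotations of the peaks (one-sided permutation p = 0.0099 for each, the smallest possible).

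Within marked genes the mark rose from the start to the end of the gene. In 6491 marked genes of at least 10 kb, peaks covered 12.6 ± 0.991% of part 1 of 10 equal parts of the gene, 34.8 ± 3.53% of part 2 and 66.3 ± 6.03% of part 9 (SD, n = 2). Part 10 had 64.8 ± 6.11%, and cover fell to 25.2 ± 2.75% in the 10 kb downstream (SD, n = 2). Cover of part 10 exceeded that of part 1 5.10 times in replicate 1 and 5.21 times in replicate 2. In 7660 unmarked genes, also of at least 10 kb but not matched on length, no part passed 3.12%. Low cover of these genes follows from the call at 10% of the span. Exonic bases of the marked genes were covered to 65.4% and intronic bases to 49.6%, a ratio of 1.34 in replicate 1 and 1.31 in replicate 2. Exon cover exceeded intron cover in 5041 of these genes, or 77.7%. Compared within each part, which was added after the data were seen, exons were below introns in part 1 (ratio 0.826) and furthest above them in part 3 (2.17), with a ratio of 1.15 in part 10. The comparison within parts is not on the scale of the profile. In part 1 exons had 13.9% and introns 16.8%, against 12.5% for the whole part by the same peaks. Gene length was not held equal, so its share in these ratios is unknown. No test was made of these values with 2 replicates.

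**Figure D3:**
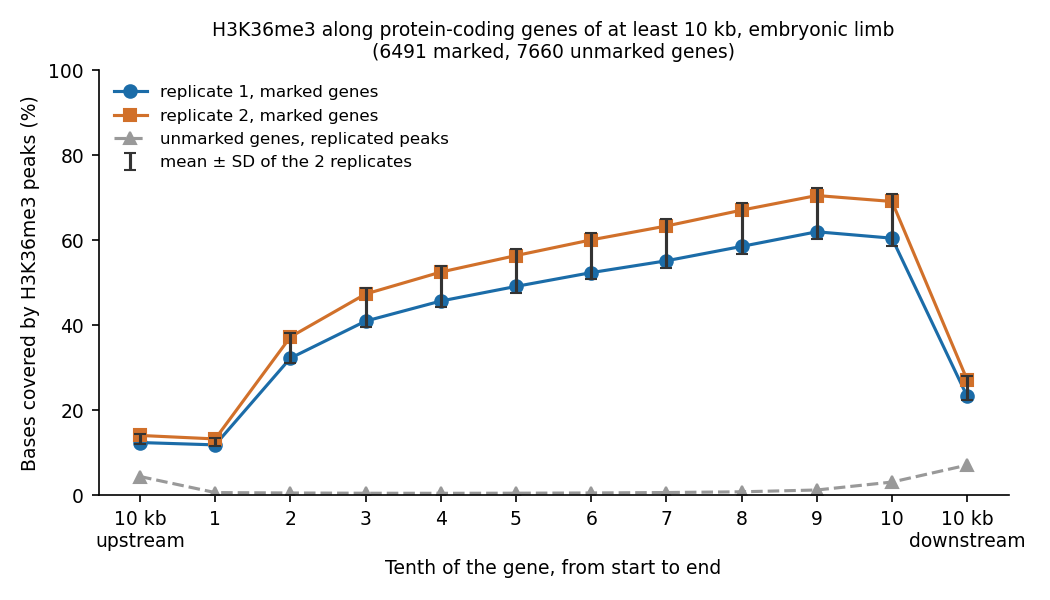
Percent of bases covered by H3K36me3 peaks (y axis) in the 10 kb upstream, 10 equal parts of the gene and the 10 kb downstream (x axis), for marked genes in replicate 1, replicate 2 and as mean ± SD of both, and for unmarked genes. Cover climbs from 12.6% in part 1 to 66.3% in part 9 and falls to 25.2% downstream.

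Of the 21196 protein-coding genes tested, 8676 (40.9%) were marked, with a median cover of 53.9% and quartiles of 31.5% and 73.1%. No replicated peak base fell in 10262 genes. The most completely covered genes of at least 10 kb included Fn1, the fibronectin gene (95.6%), the splicing factor genes Sf3b3 (95.5%), Sf3a1 (94.8%) and Sfpq (94.8 ± 0.563%, SD, n = 2), and Mcm5 of the replicative helicase (94.8%). Trrap, a subunit of histone acetyltransferase complexes, reached 96.1% and Nedd4, a ubiquitin ligase, 94.8%, with Khdc4 at 95.4%, Gm42715 at 95.3% and 1700109H08Rik at 99.3%. Among the marked genes, 775 shared at least 50% of their span with another coding gene, so that their cover is not theirs alone. Gm42715 was among these, with 99.4% of its span shared. The strongest peak by the authors' signal, 26.6, lay at chromosome 9, 22276544 to 22281072, over coding sequence and untranslated sequence of the zinc finger gene Zfp810. The next, with a signal of 24.6 at chromosome 7, 5027338 to 5034212, overlapped Zfp865, Ccdc106, Gm44973 and 4632433K11Rik. The remaining peaks of the top 5 were a pair in introns of the noncoding gene AI506816 (chromosome 5, 23703603 to 23704894 and 23707212 to 23707518) and one over coding exons of Shroom3 (chromosome 5, 92939573 to 92944212), with signals from 24.2 to 24.3.

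Transcription factor genes of the limb field and its mesenchyme were marked at 21 of 29 members. Tbx5 had the highest cover of the list (83.0 ± 0.747%, SD, n = 2), followed by Prrx1, a homeobox gene of limb mesenchyme (74.5 ± 3.16%). The posterior factor Hand2 had 25.8 ± 10.7%, the Hedgehog effector Gli3 24.9 ± 2.97%, the dorsal factor Lmx1b 26.1 ± 1.08% and the proximal factor Meis1 26.1 ± 1.11%. The ventral ectoderm gene En1 had no peak in either replicate, and Emx2 had 1.62% in replicate 1 and 0 in replicate 2. The list median was 25.4% against 0 to 22.0% for the central 95% of 10000 random lists matched on gene length (two-sided permutation p = 0.0322, adjusted p = 0.106), so the planned test did not pass after adjustment over 33 lists. It passed in the same permutation test with replicate 1 alone (median 26.9%, adjusted p = 0.0350) and not with replicate 2 alone (median 25.3%, adjusted p = 0.139) or in any other setting of that test. The number of marked members, a test added after the data were seen, exceeded the mean of 11.5 in random lists (permutation, adjusted p = 0.00132).

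Genes of the limb's signalling pathways divided by member. Of 33, 19 were marked, led by the Wnt target Axin2 (71.9 ± 0.934%, SD, n = 2) and the fibroblast growth factor effector Etv5 (62.5 ± 3.85%), while the ridge signal Fgf8 (1.06% and 0 in the replicates), the posterior signal Shh (0 in both), Aldh1a2 and Dkk1 had no replicated peak. The BMP antagonist Grem1 had 14.1 ± 0.481% (SD, n = 2). Their median of 14.0% lay within the random lists (permutation, adjusted p = 0.647), and so did the number marked (adjusted p = 0.141). Of the HoxA and HoxD genes of paralogue groups 8 to 13, 4 of 10 were marked, namely Hoxa9, Hoxa10, Hoxa11 and Hoxd10, with Hoxa10 at 46.4 ± 9.37% and Hoxa9 at 51.4 ± 10.7% (SD, n = 2). Hoxa13 had no peak in either replicate, and Hoxd13 and Hoxd12 had 3.37% and 2.79% in replicate 1 only. Of groups 1 to 7, 6 of 10 were marked, led by Hoxa5 (74.7%) and Hoxa4 (36.2%), while Hoxa1 and Hoxa2 had no peak. Those 6 shared nearly all of their annotated spans with other coding genes, at least 98.6% each. The medians of these lists, 5.84% for groups 8 to 13 and 14.7% for groups 1 to 7 (19.8% in replicate 1 and 10.8% in replicate 2), did not pass against random lists (permutation, adjusted p = 0.875 and 0.647). None of 10 HoxB and 9 HoxC genes was marked (adjusted p = 0.0489 and 0.0366 in the added permutation test of marked members), with Hoxb3 highest at 3.76% (8.34% in replicate 1 and 2.58% in replicate 2) and Hoxb1, Hoxb13, Hoxc10 and Hoxc11 at 0.

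Matrix and receptor genes of mesenchyme were marked at 11 of 20 members, from Fn1 (95.2 ± 1.39%, SD, n = 2) and Fbn2 (87.0% by the replicated peaks) to Dcn and Lum at 0, and their median of 21.0% (11.6% in replicate 1 and 31.6% in replicate 2) did not pass against random lists (permutation, adjusted p = 0.575). Cartilage genes were marked at 3 of 14, namely Col2a1 at 76.2 ± 11.2%, the chondrogenic regulator Sox9 at 31.4 ± 10.9% (SD, n = 2) and Col9a1 at 15.4% (9.02% in replicate 1 and 21.9% in replicate 2), while Acan (0.131% in replicate 1 only) and Col11a2 (0.239% and 1.52%) had no replicated peak. Replicate 1 alone marked 2 cartilage genes and replicate 2 alone 4, with medians of 0.271% and 2.96%. Neither the cartilage median of 0.242% nor the number of marked members differed from random lists (permutation, adjusted p = 1 and 0.217). None of 11 genes of bone and hypertrophic cartilage was marked, with Col10a1 highest at 4.56%, Runx2 at 0.412%, and Alpl and Dmp1 at 0 (adjusted p = 0.0175 in the added permutation test). Col10a1 lay wholly within spans of other coding genes, so its cover is not its own alone. Muscle precursor genes were marked at 1 of 14, the homeobox gene Six4 (69.3 ± 5.76%, SD, n = 2). Six1 had 7.09% (2.68% in replicate 1 and 9.35 percentage points more in replicate 2), the precursor marker Pax3 had 0.279% in replicate 1 and 0 in replicate 2, and Lbx1 and Mef2c had none (adjusted p = 0.0456 in the added permutation test). None of 18 genes of differentiated skeletal muscle was marked, with Ryr1 at 7.22%, Mylpf at 2.22%, Acta1 at 2.18% in replicate 1 only and Actn3 at 0 (adjusted p = 0.00132 in the same permutation test). Acta1 likewise lay wholly within spans of other coding genes.

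Marker genes of other cell types were covered rarely. None of 17 genes of limb ectoderm and ridge epithelium was marked, with Krt18 at 3.04%, Dsp at 1.95% (4.99% in replicate 1 and 0 in replicate 2), Cdh1 at 0.0972% in replicate 1 only and Cldn6 at 0. Of 16 endothelial genes only the transcription factor gene Fli1 was marked by the replicated peaks (57.3 ± 11.5%, SD, n = 2), with Egfl7 at 7.00% by the replicated peaks but past the threshold in each replicate alone (10.9% and 10.2%), and no replicated peak in Cdh5 or Emcn (1.59% and 0.0713% in replicate 1 only). Egfl7 shared 49.5% of its span with other coding genes. Of 15 erythroid genes, the transferrin receptor gene Tfrc (73.5%) and Alas2 (27.7%) were marked, while Epor had 6.44% (11.3% in replicate 1 and 9.67% in replicate 2), Ank1 had 0.0592% in replicate 1 only and Gata1 had no peak. Alas2 lay wholly within the span of another coding gene. Of 14 macrophage genes, Cd68 (100%), Fcer1g (22.1%) and Cx3cr1 (20.3%) were marked, with Adgre1 at 0 and Aif1 at 1.28% in replicate 1 only. The peak over Cd68 ran from 69663572 to 69666977 on chromosome 11, spanned all of Cd68 and reached 42 bases into the neighbouring gene Eif4a1. Of 14 lymphocyte genes only Foxp3 was marked (19.8%), with Lck at 2.40% and Cd19 and Cd3d at 0. No gene was marked among 21 of neurons, 11 of neural crest, Schwann cells and melanocytes, 15 of heart muscle, 18 of hepatocytes and 17 of pluripotent cells and the germ line. In these lists the highest covers were those of Slc17a7 (4.64%), Camk2a (0.293%), Kit (3.77%), Tnni3 (2.62%, with 1.59% and 4.74% in the replicates), Mael (1.22%) and Dazl (1.08%). Gabra1, Gad1, Dct, Ednrb, Actc1, Gata4, Afp, Ahsg, Dppa3 and Dppa4 had no replicated peak, and of these only Gata4 had a peak in a replicate (0.357% in replicate 1).

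The list medians of these cell types were 0, and the lower end of the central 95% of random lists was also 0 for each. The planned permutation test could therefore not have called them low, and none passed it. In the added permutation test, the number of marked members was below that of length-matched random lists for ectoderm (adjusted p = 0.00132), endothelium (0.00917), lymphocytes (0.0192), neurons (0.00110), neural crest (0.00738), heart (0.00412), hepatocytes (0.000733) and germ line (0.00110). Erythroid genes (adjusted p = 0.0623) and macrophage genes (0.493) did not pass this permutation test.

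Genes that all proliferating cells use were covered over most of their length. All 28 spliceosome and RNA-binding genes were marked (median 84.3%), from Sf3b3 at 95.5% to Hnrnpk at 69.0% and Prpf6 at 61.2%. All 31 proteasome genes were marked (median 75.1%), from Psmc6 at 89.7% and Psmc4 at 88.8% to Psma2 at 29.5% and Psmd14 at 10.6% (9.27% in replicate 1). Cell cycle and replication genes were marked at 24 of 25 (median 81.5%), led by Mcm5 and Top2a (94.0%), with Pcna at 50.8% and the exception Pola1 at 6.27%. Ribosomal protein genes were marked at 49 of 50 (median 68.0%), led by Rps3 (86.6%) and Rps5 (82.1%), with Rps23 at 17.5% and the exception Rps14 at 8.35%. Respiratory chain genes were marked at 29 of 30 (median 66.3%), led by Ndufa10 (87.9%) and Uqcrc2 (87.0%), with Ndufa1 at 11.9% (5.12% and 5.20% in the replicates) and the exception Ndufs4 at 8.70 ± 2.51% (SD, n = 2). Genes of H3K36 methyltransferases, demethylases and readers were marked at 15 of 16 (median 75.4%), with Kdm4a at 92.7%, Psip1 at 89.1%, Dnmt3a at 27.8% and the exception Phf19 at 0.853% in replicate 1 only. Setd2, the methyltransferase that makes H3K36me3, had 76.4 ± 5.91% (SD, n = 2). Each of these 6 medians lay above 10000 length-matched random lists (two-sided permutation, adjusted p = 0.000943, the smallest that could be reached here). Glycolysis genes were marked at 13 of 16 (median 55.4%, permutation, adjusted p = 0.0462), with Gpi1 at 93.0% and Pkm at 86.7%, against Pfkp at 3.34% and Slc2a3 at 0 (0.349% and 0.479% in the replicates). That call was lost in the permutation test with peaks of −log10 q of at least 2 (adjusted p = 0.0503).

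**Figure D4:**
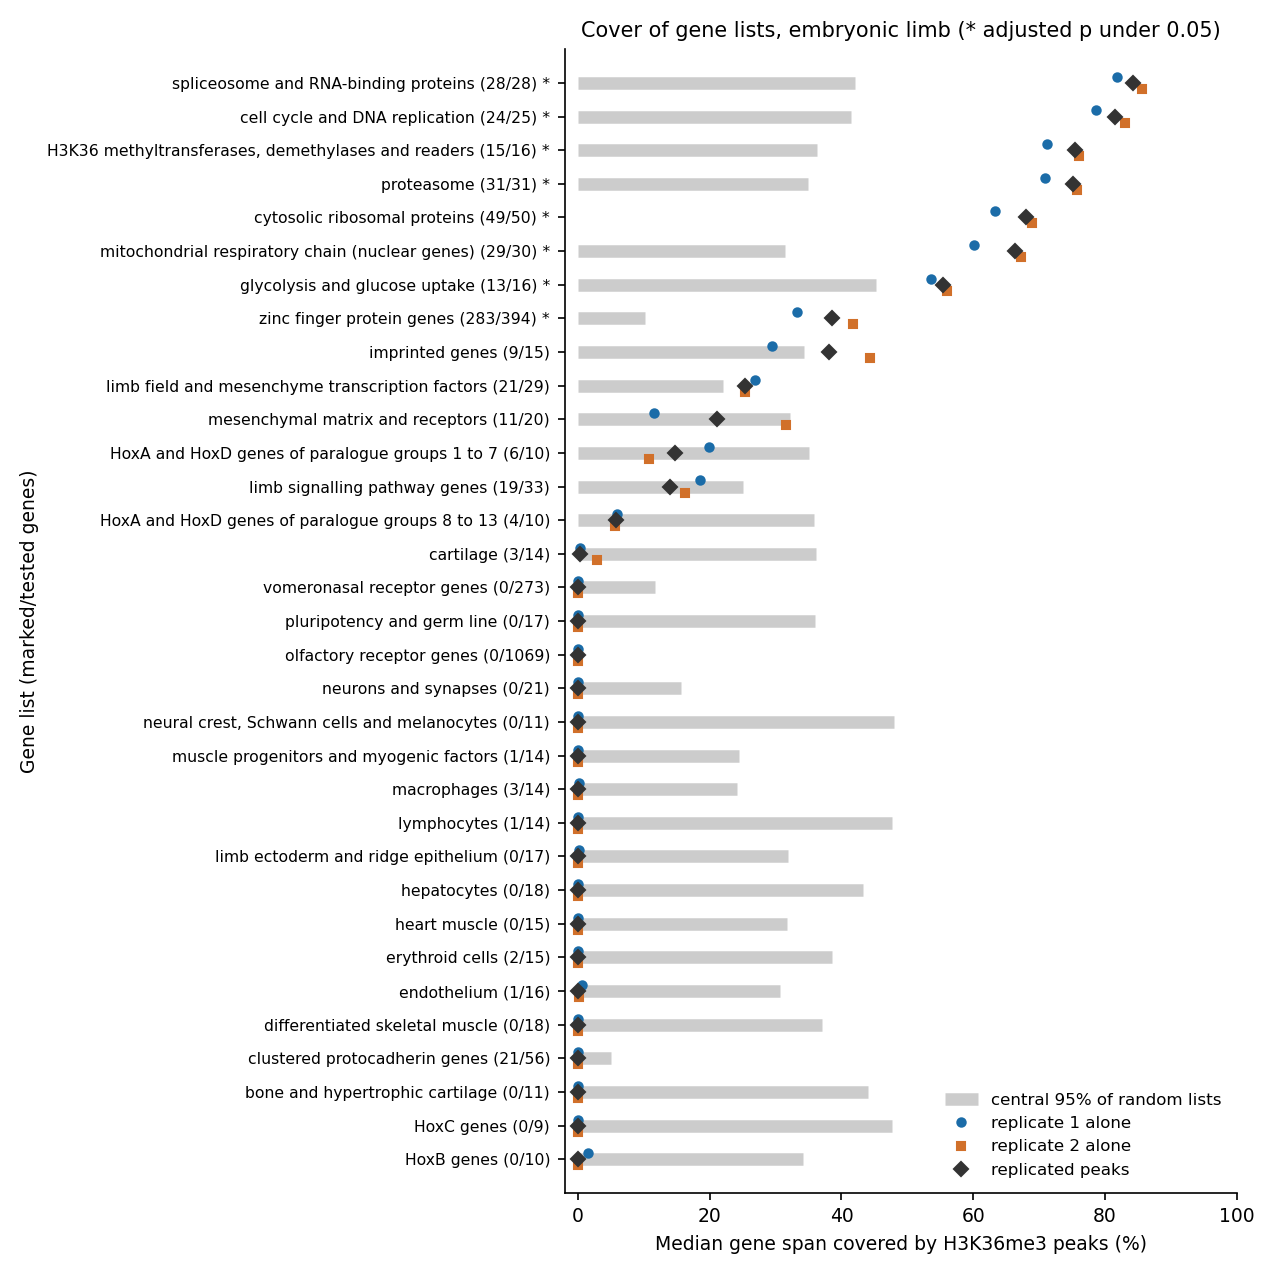
Median percent of gene span covered (x axis) for 33 gene lists with marked and tested members in parentheses, as replicated peaks, replicate 1 alone and replicate 2 alone, with bars for the central 95% of length-matched random lists and asterisks for an adjusted p under 0.05. The 8 lists with asterisks are those of genes used by all cells and the zinc finger genes, from 84.3% for the spliceosome to 38.5% for zinc finger genes.

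Large gene families went opposite ways. Zinc finger protein genes named Zfp were marked at 283 of 394, with a median of 38.5% against 0 to 10.2% in random lists (permutation, adjusted p = 0.000943), from Zfp869 (96.5%) and Zfp335 (91.7%) to Zfp114 at 0 and Zfp174, which had 0.741% in replicate 1 and 3.07% in replicate 2. None of 1069 olfactory and 273 vomeronasal receptor genes was marked (adjusted p = 0.000733 for each in the added permutation test of marked members). Olfr543 had 1.84%, while Olfr1, Olfr10, Vmn1r1 and Vmn1r10 had 0. Clustered protocadherin genes were marked at 21 of 56, led by Pcdhgc4 (69.0%) and Pcdhgc5 (68.1%), and Pcdha1 and Pcdha11 had no peak. Neither their median of 0 nor the number marked differed from random lists (permutation, adjusted p = 1 and 0.537), and the spans of these genes overlap. Among genes of at least 5 kb alone their median lay 47.0 percentage points above random lists (permutation, adjusted p = 0.000825). Imprinted genes were marked at 9 of 15, led by Peg3 (85.1%) and Igf2r (81.7%), with Ndn and Phlda2 at 0 (median 38.1%, with 29.5% in replicate 1 and 44.4% in replicate 2; permutation, adjusted p = 0.106).

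The X chromosome carried less of the mark than any autosome. Peaks covered 4.88% of protein-coding gene span on X, against a median of 13.9% and a range from 10.2% on chromosome 6 to 20.1% on chromosome 11 for the 19 autosomes. The X share was 4.20% in replicate 1 and 5.32% in replicate 2. Of 877 X genes 23.0% were marked, against 32.9% to 51.8% on the autosomes. None of 163 Y genes was marked, although peaks lay in the Y genes Kdm5d (2 peaks) and Ddx3y (4 peaks).

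**Figure D5:**
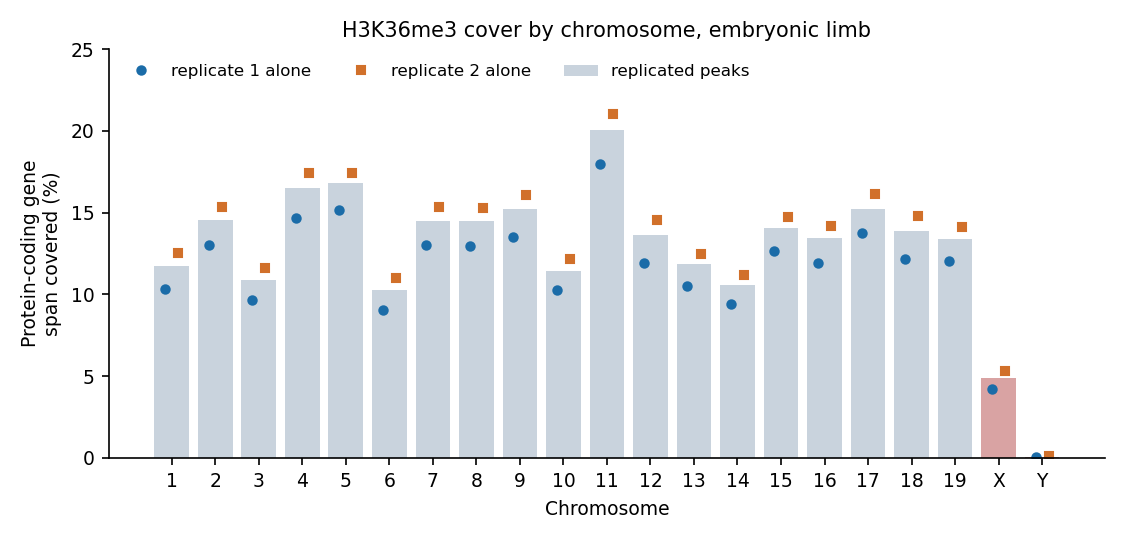
Percent of protein-coding gene span covered by replicated H3K36me3 peaks (bars), by replicate 1 alone (circles) and by replicate 2 alone (squares), for each chromosome. The X bar, at 4.88%, lies below all 19 autosomes, which range from 10.2% to 20.1%.

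Gene structure went with the mark. Single-exon genes were marked at 146 of 872 (16.7%) and multi-exon genes at 8530 of 20324 (42.0%), an odds ratio of 0.278 (two-sided Fisher's exact test across genes, p = 3.04e-55). The share marked was 15.1% for genes of 1 to 2 kb, 51.5% for 20 to 50 kb and 12.1% beyond 200 kb. Fisher's test did not match genes on length, so exon number and length cannot be told apart here. Of long intergenic noncoding RNA genes outside coding genes, 85 of 4963 (1.71%) were marked.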

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

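All tests here were chosen after the main results were seen, and those of the replicate difference on the fixed gene lists (the count of limb genes replaced earlier tests of wider calling on picked genes and on the list median), of X gene content and of X signal also after their own values were seen. Peaks outside the main chromosomes and outside annotated Y genes belong to no comparison above. The replicated list held 13 peaks on scaffolds not placed on the main chromosomes. The strongest, with a signal of 20.9 at positions 30510 to 36110 of a chromosome 4 scaffold (GL456216), ranked 16 in the whole list, and another chromosome 4 scaffold (JH584295) held a peak ranked 96. On the Y chromosome 23 of 29 replicated peaks lay outside annotated genes, all between 90718189 and 90745846, with a highest signal of 10.4 against 4.90 in Ddx3y. No control sample was used here for either, and no explanation was tested.

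The difference between the replicates was not the same for all lists of marked genes: in a permutation test of the median of replicate 2 minus replicate 1, 7 of 19 lists passed as measured and 3 after the trend with GC content, length and cover was removed. Limb transcription factors (-0.619 percentage points as measured, -8.41 with the trend removed), signalling genes (0.681, -7.00) and HoxA and HoxD genes of groups 1 to 7 (-3.18, -8.84) were low in both. That HoxA and HoxD list held 6 genes of shared spans, 3 of them lower in replicate 2. The spliceosome (2.05, -2.11), ribosomal proteins (3.51, -1.20), protocadherins (9.91, 1.37) and HoxA and HoxD genes of groups 8 to 13 (14.2, 6.31) did not pass with the trend removed. Groups 8 to 13 nonetheless stayed above the central 95% of random lists (upper end 5.32). Protocadherin genes overlap in span and share peaks, so their members are not separate observations. Of the 21 limb transcription factor genes 11 were lower in replicate 2, against at most 7 in 10000 draws of marked genes matched on GC content, length and cover (permutation, adjusted p = 0.00190; 0.743 for HoxA and HoxD genes of groups 1 to 7), which argues against wider calling of replicate 2 as a whole at these limb transcription factor genes but does not bear on the excess at Tbx4 and Pitx1. With the trend removed, genes of the early Lin28 and let-7 timing programme had -4.70 against -3.85 to 3.50 for the central 95% of random lists. That was past the bound written first, which counts against GC content and length, and 9 of 9 members lay below the random median. It did not pass after adjustment (permutation, adjusted p = 0.0617), and the list was written after related genes had been seen to differ, so it does not decide the question. Limb transcription factors, a list fixed in advance, had -8.41 against -2.63 to 1.98 (permutation, adjusted p = 0.00127). This argues against GC content and length as the whole cause in that list. For a later stage of the second pool, the early genes, listed after Lin28a, Prtg and Igdcc3 had been seen to differ, met their bound as measured (1.84 against 2.28 to 10.3; permutation, adjusted p = 0.0537), while genes of maturing mesenchyme did not (7.35 against 2.29 to 10.5); the rule written first would have counted this against that stage and was relaxed afterwards, because 8 marked genes inside that band exclude no modest shift, so stage stays open, as do dissection and the shares of forelimb and hindlimb tissue, which were not tested.

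The low cover of the X chromosome was not matched by autosomal genes of like GC content and length. In 1000 draws of such genes a median of 35.5% were marked (central 95% 32.6% to 38.2%) against 23.0% on X. Without matching the median of the 19 autosomes was 43.1%, so matching took up part of the gap. This argues against GC content and length as the whole cause. Fewer transcribed genes on X, acting alone, would leave the marked ones like others. The median cover of marked X genes was 35.5% against 54.9% in matched marked autosomal genes (central 95% 49.6% to 60.3%). This argues against fewer transcribed genes as the whole cause, and cannot exclude them as a part of it. The signal of peaks in marked X genes, weighted by width, was 4.93, below all 19 autosomes (6.11 to 6.98). Their unweighted median signal was also below all autosomes but by much less, at 3.55 against 3.72 to 3.89. Both values go with 1 active X in each cell and fewer X copies in a pool of both sexes. Whether the signal was set against a control that holds the same copies is unknown, and no sample of a single sex was analysed here, so that explanation stays a hypothesis.

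Zinc finger genes took a large share of the strongest peaks, 28 of the top 100 and 13.6% of the top 500, against 2.11% of all peaks. Peaks matched to the top 500 on GC content and width gave a median of 2.2% and at most 4.8% in 1000 draws, so the share was 6.18 times the matched one, which argues against GC content. Of the 50-base words in those zinc finger peaks 99.3% occurred once in the genome, against 99.2% in the other strong peaks. This argues against reads shared between copies identical over 50 bases. Copies that differ by a single base in a word count as distinct here, and the aligner is unknown. Sharing between near-identical copies therefore stays open. The design gives no group that bears on a biological explanation, and none was tested.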

How the results depend on the processing

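The count of marked members, the comparison within parts of the gene and the use of peaks found in both replicate lists were chosen after the data were seen. No paired analysis was possible because there was 1 group. With 2 replicates and unknown depth, no value here has a test between animals, and weak cover cannot be told from none. All location ratios kept their direction, the number of marked genes ranged from 7595 (20% of the span) to 9375 (5%), and the odds ratio of single-exon genes from 0.258 to 0.287.

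Values that moved by more than the replicates differed were the following, and the cause was not tested. The correlation of signal was 0.679 with an overlap of 50% and 0.606 with −log10 q of at least 2. Part 10 of the gene over part 1 was 5.08 to 5.21 without either replicate, 4.85 with pooled peaks, 4.93 with merged peaks and 5.61 with peaks found in both lists. Exons over introns gave 1.25 merged and 1.66 within parts, and X over autosomes 0.367 pooled and 0.390 merged. The value within parts is a mean of 10 ratios and is not on the scale of the main one. Of the list medians, limb transcription factors passed the permutation test without replicate 2 (25.7 points above random lists, adjusted p = 0.0350) and not without replicate 1 (24.0), and so did vomeronasal genes (-2.72 and -3.54) and, without length matching, olfactory genes (-1.79). Glycolysis was lost at the stricter q (48.5, permutation, adjusted p = 0.0503), and protocadherins turned from below to 47.0 above among genes of at least 5 kb, a set without their short members.

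Counts of marked members passed for 16 lists whose medians had not, and the cause was not tested. The differences from random lists were 9.52 for limb transcription factors, -3.28 for HoxB, -3.33 for HoxC, -6.55 for ectoderm, -4.03 for muscle precursors, -7.50 for skeletal muscle, -4.10 for bone, -5.60 for endothelium, -4.79 for lymphocytes, -7.45 for neurons, -4.75 for neural crest, -5.40 for heart, -7.79 for hepatocytes, -6.77 for germ line, -435 for olfactory and -123 for vomeronasal genes.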

Other observations

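The tests of zinc finger neighbours and the choice of the genes with the largest replicate differences were made after the results were seen, while the list of noncoding genes was written before their values. Long noncoding RNA genes differed widely in cover. The imprinted gene Meg3 had 78.9% of its span covered by replicated peaks, Tug1 77.3% and Malat1 76.8%. H19, the imprinted neighbour of Igf2, had 54.2%. Peaks have no strand, so cover of a span shared with coding genes is not that of the noncoding gene alone. Airn had 38.2%, with 39.9% of its span shared, and 38.5% of the rest was covered. Dnm3os (35.9%) and Kcnq1ot1 (28.0%) lay wholly within coding genes. Xist, which silences an X chromosome in female cells, had 30.4%, with 93.2% of its span shared and no peak in the rest. Hottip and Hotair of the HoxA and HoxC clusters had no peak, Neat1 had 0.313% in replicate 1 only, and Hand2os1 had 3.72% (1.88% outside coding genes). Among intergenic noncoding genes of at least 10 kb outside coding genes, 1700020I14Rik (79.6%) and D930016D06Rik (79.2%) were the highest, above Meg3, and Mirg, in the same region of chromosome 12 as Meg3, had 75.3%. These genes, and Ftx next to Xist with 49.3%, were chosen after their values were seen, Meg3 excepted.

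The most covered X genes were Itgb1bp2 (98.1%), Med12 (91.5%) and Hcfc1 (89.5%), followed by Asmt, the histone demethylase gene Kdm5c, Maged1 and Flna at 77.3% to 81.4%. With peaks under 1 kb apart merged, only 1 region of at least 5 kb lay over 10 kb from every annotated gene. It ran from 104580191 to 104588250 on chromosome 5, with a highest signal of 16.9, and was covered to 63.8% in replicate 1 and 79.5% in replicate 2. The noncoding gene D930016D06Rik ended at 104554207 on the same chromosome.

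Among marked genes of at least 10 kb, the largest excess in replicate 2 was at Mxd4 (22.1% and 67.1%), Crat (28.7% and 68.1%), Tbx4, Tgfb3, Adamts7 (15.5% and 47.3%), Ilvbl (34.9% and 65.2%) and Cxcl12 (38.1% and 68.0%). The largest excess in replicate 1 was at Lin28a (32.8% and 17.2%), Rspo4 (26.3% and 12.8%), Igdcc3 (69.3% and 57.3%), Hoxd4 and Prtg (56.0% and 44.6%). These genes were chosen for their difference, and Isl1 and Hoxc10, which mark hindlimb as Tbx4 and Pitx1 do, had no peak in either replicate.

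Zinc finger genes with another such gene within 200 kb were marked at 171 of 246 (69.5%) and those without at 112 of 148 (75.7%), so the mark was frequent in both.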
